A study of Escherichia coli K-12 with 9 samples.

How the data were processed

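RNA-seq counts of 9 libraries were used, 3 from each of 3 strains: cells with the empty vector, with wild-type pIV and with pIV-E292K. The labels give 3 independent colonies per strain and state no batch. Per the file headers and the authors' processing notes, the deposited count values are raw counts per annotated feature, made with CASAVA 1.8, Trimmomatic 0.30, Bowtie2 2.1.0 and DESeq2 1.6. The roles of these programs, the counting program, the genome build, the annotation and the strand setting are not given in the sources used here. The authors also deposited tables for the comparisons with vector, whose log2 fold changes and their standard errors come from DESeq2, per the file headers. Their FDR values are false discovery rates from the same tables, per the file headers, and the filter behind the 2976 features listed is not given in the sources used here.

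Of 4260 features counted, 2972 carried a symbol, taken from the authors' deposited tables, and 1288 had none. A symbol shared by several features (55 features) was left out of the gene lists. Only list members matched to a feature with an unshared symbol were tested, and counts of list genes refer to these. Of the fixed lists, 17 of 44 iron, 16 of 29 sigma E, 31 of 50 flagella and 11 of 20 colanic acid genes were tested. For histidine, aromatic and arginine genes it was 3 of 8, 9 of 15 and 8 of 11. Of 2967 chromosomal symbols, 2915 were found in the reference table of names, which was used for synonyms only, so no coordinates are given. Of the features, 52 had 0 counts in all libraries, and 4188 passed filterByExpr. A floor of 3 counts covers counting error only.

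Counts were fitted in 1 model over the 9 libraries with a mean per group in edgeR 4.0.16 (R 4.3.3), with TMM scaling and the quasi-likelihood F-test. The 3 contrasts were each adjusted by the Benjamini-Hochberg method, at an adjusted p of 0.05. Standard errors of log2 fold changes were taken from the F statistic, and levels are CPM with TMM scaling as mean ± SD of 3 libraries. Across all genes the biological coefficient of variation was 0.285. In simulated data with 200 changed features, 44%, 52% and 52% of 2-fold changes and 88%, 88% and 89% of 4-fold changes were called in the 3 contrasts, and 2.22%, 6.04% and 5.37% of calls were false. Log2 fold changes from the fit had Pearson correlations across genes of 0.994 and 0.993 with those in the authors' deposited tables. Among the 2976 features in those tables, 2029 and 1627 were called in both the same way and none the opposite way, 72 and 5 were called here only, and 291 and 281 in the authors' tables only.

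The 39 gene lists, the rule for named genes, the tests and the alternatives in this paragraph were fixed before the data were examined. The lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation and with fry. With the preset correlation 19 lists were called in wild-type pIV against vector, 20 in pIV-E292K against vector and 15 in pIV-E292K against wild-type pIV, and with an estimated correlation 0 in each. The estimated correlation was 0.970 for NADH dehydrogenase I, 0.827 for the TCA cycle, 0.777 for ribosomal proteins and 0.0180 for anaerobic respiration. Where it is high, the genes of a list are not separate observations, and the preset value treats them as nearly independent. Genes named in each comparison were the 10 highest and 10 lowest log2 fold changes among genes called, with groups that did not overlap and a mean of at least 10 CPM. Only features with an unshared symbol were named, so stronger changes of other features were passed over. Among features higher in wild-type pIV against vector, 19 such features ranked above the last of the 10 named. Of each list, up to 4 members with the smallest adjusted p were added, with every phage shock gene and the checks of strain and plasmid. Alternatives were size factors of DESeq2 1.42.0, total-count and upper quartile scaling, no filter on low counts, at least 10 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, only the 6 libraries compared, the replicate number as a block, adjusted p under 0.01, at least 2-fold, and each library left out. Overlap between the comparisons with vector was set beside 50 simulations of unchanged groups. In these all 9 libraries were drawn anew around the vector mean, and both comparisons shared the simulated vector group.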

Results

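RNA was measured by sequencing in Escherichia coli K-12 carrying 1 of 3 plasmids: the empty vector, a derivative that expresses the filamentous phage protein pIV, or a derivative that expresses pIV with the E292K substitution. pIV is the outer membrane channel (secretin) through which filamentous phage leave the cell, and the strain is a lamB deletion derivative of MC4100, per the labels. Each group held 3 libraries, made from cultures of separate colonies. Cultures of all groups grew at 37 °C with chloramphenicol at 25 µg/mL. Expression was induced with 1 mM IPTG at an optical density of 0.2, and cells were harvested 1 hour later. Vector libraries held 49150400, 34762800 and 31027900 counts for replicates 1 to 3. The wild-type pIV libraries held 31494200, 29833900 and 23597400 counts, and the pIV-E292K libraries 9474410, 26716700 and 24963500 counts. A floor of 3 counts was worth between 0.0770 and 0.279 CPM, which covers counting error only. In vector replicate 1, 54.3% of the counts lay in 7 features with no symbol, against 0.0763% to 4.76% in the other libraries.

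The phage gene was measured before the comparisons because it checks the labels. gIV, which encodes pIV, lay at 20977 ± 3826 CPM (SD, n = 3) with wild-type pIV and at 7272 ± 1534 CPM with pIV-E292K. In the vector libraries it lay at 5.06 ± 3.12 CPM, from 194, 127 and 102 counts, whose origin cannot be told from the counts. The pIV-E292K mean was 34.7% of the wild-type mean, a log2 difference of -1.53 ± 0.40 (SE, edgeR adjusted p = 0.0283). That call was lost without any 1 of the 6 libraries of those groups, with adjusted p values up to 0.1 over the 9 fits that left out a library, while the log2 difference stayed between -1.64 and -1.36. The plasmid chloramphenicol resistance gene cat lay at 46079 ± 7373 CPM with vector, 23457 ± 10066 CPM with wild-type pIV and 9920 ± 4466 CPM with pIV-E292K. The plasmid lac repressor gene lacIq lay at 4984 ± 737 CPM with vector, 27586 ± 12626 CPM with wild-type pIV and 2036 ± 163 CPM with pIV-E292K. A beta-galactosidase row that the authors' deposited table describes as a reporter absent from the strain lay at 1.01 ± 0.32 CPM with vector, 1.10 ± 0.17 CPM with wild-type pIV and 1.81 ± 0.22 CPM with pIV-E292K. From 20 to 52 counts per library, it was still called higher in pIV-E292K against vector (0.83 ± 0.29, edgeR adjusted p = 0.0456). A call at so few counts can thus fall on a feature described as absent. The deleted gene lamB was not analysed here, because no row used here names it.

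**Figure D1:**
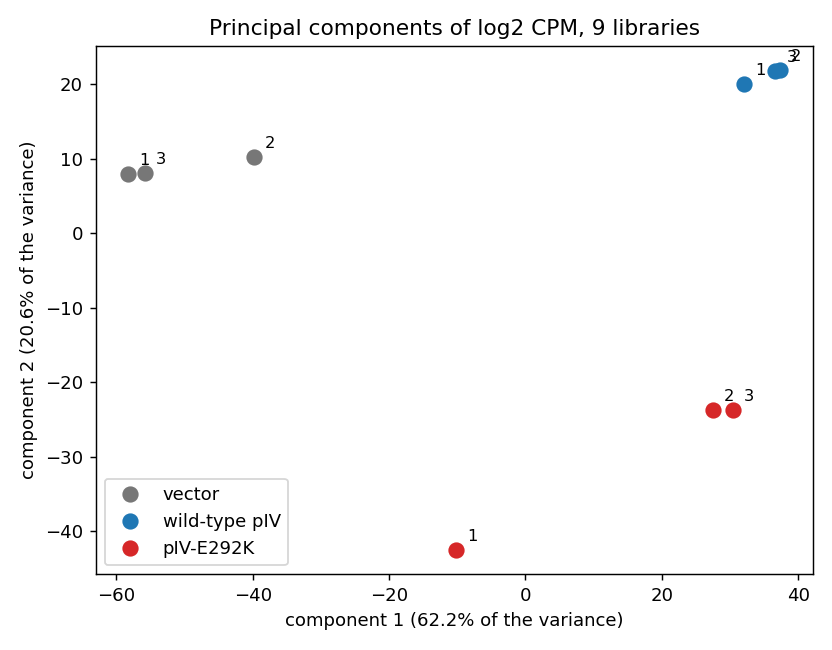
Principal components of log2 CPM. Each point is 1 of the 9 libraries with its replicate number, coloured by group, with component 1 (62.2% of the variance) on the horizontal axis and component 2 (20.6%) on the vertical axis. Vector libraries lie between -58.2 and -39.9 on component 1 and wild-type pIV libraries between 32.1 and 37.3, while pIV-E292K replicate 1 lies at -10.2 and its replicates 2 and 3 at 27.5 and 30.4.

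Wild-type pIV was compared with the vector to ask which host genes differ when the channel is made. Of the 7 phage shock genes, which respond to damage at the inner membrane, 5 rose, each by more than 3 on the log2 scale, and 2 fell. All 4 osmoprotectant uptake genes, 15 of 17 iron genes, 12 of 13 methionine genes and 44 of 53 ribosomal protein genes rose. In sugar uptake 20 of 21 genes fell, in the TCA cycle 14 of 15, in NADH dehydrogenase I 13 of 13, in the maltose regulon 9 of 10 and in anaerobic respiration 21 of 32. Of 4188 features tested, 1296 were higher and 1173 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The calls made up 59.0% of the features. The 3 libraries of each group did not overlap for 68.1% of features, where chance gives 10%.

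In wild-type pIV, 5 of the 7 phage shock genes rose and 2 fell. pspA, whose product binds the inner membrane, went from 55.4 ± 8.25 to 584 ± 27.3 CPM (log2 fold change 3.40 ± 0.35, adjusted p = 0.000190). pspB rose by 3.86 ± 0.19, pspC by 3.74 ± 0.19, pspD by 3.77 ± 0.21 and pspG by 3.17 ± 0.25. pspE, which encodes a sulfurtransferase, fell by 1.40 ± 0.27, and pspF, the activator of the operon, fell by 0.73 ± 0.14. The phage shock (psp) list stood above the other genes (camera adjusted p = 0.0292, and adjusted p = 0.515 with an estimated correlation). In the SoxRS and OxyR list 5 genes rose, 3 fell and 4 did not pass. soxS, the activator of the superoxide response, went from 16.4 ± 1.2 to 570 ± 55.1 CPM (log2 fold change 5.12 ± 0.18, adjusted p = 3.30e-06), and marA rose by 2.15 ± 0.21 while ahpC fell by 0.60 ± 0.15. The oxidative list as a whole did not stand apart (camera adjusted p = 0.406).

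All 4 osmoprotectant uptake genes rose with wild-type pIV. proW and proV, of the glycine betaine transporter, rose by 4.02 ± 0.24 and 3.66 ± 0.26, and proP rose by 3.76 ± 0.32 (camera adjusted p = 0.00190, and adjusted p = 0.515 with an estimated correlation). Of 17 iron genes, 15 rose and 2 did not pass, among them fhuA (3.06 ± 0.32), tonB (2.36 ± 0.27), nrdH (3.60 ± 0.42) and sufA (2.01 ± 0.21); the list gave camera adjusted p = 2.78e-05, and adjusted p = 0.515 with an estimated correlation. ryhB, a small RNA of iron starvation, went from 0.482 ± 0.211 to 21.8 ± 8.85 CPM (log2 fold change 5.44 ± 0.80). In the phosphate starvation list 8 genes rose, 3 fell and 1 did not pass, and pstS rose by 4.39 ± 0.33 and phoB by 2.20 ± 0.19, while the list itself was not called (camera adjusted p = 0.0745). The argF-lac list was fixed as a strain check, since MC4100 carries a deletion of that region. Of its 26 genes, 3 were measured, each with counts in all 9 libraries. The others were matched to no feature used, so the check could not show whether the region is absent. Whether these 3 lie inside the deletion was not tested. All 3 rose. mhpD went from 2.02 ± 0.46 to 23.2 ± 0.54 CPM, mhpF rose by 2.52 ± 0.25 and mhpE by 1.58 ± 0.20 (camera adjusted p = 0.0227, and adjusted p = 0.515 with an estimated correlation).

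Of the 13 methionine genes, 12 rose and 1 fell with wild-type pIV. metF rose by 4.49 ± 0.36, metR by 3.28 ± 0.27, metA by 1.74 ± 0.13 and metI by 1.67 ± 0.12 (camera adjusted p = 0.000100, and adjusted p = 0.515 with an estimated correlation). Of 53 ribosomal protein genes, 44 rose and 9 did not pass; rplD went from 954 ± 308 to 3661 ± 383 CPM and rpsL from 932 ± 225 to 2978 ± 154 CPM (camera adjusted p = 8.24e-08, and adjusted p = 0.515 with an estimated correlation). All 3 tested histidine genes, of 8 in the fixed list, rose, as did 7 of 9 tested aromatic amino acid genes and 6 of 8 tested arginine genes (camera adjusted p = 0.0292, 0.0183 and 0.0292). With an estimated correlation each of these 3 lists had adjusted p = 0.515. In the aromatic list, tnaB, a tryptophan permease gene, fell by 5.77 ± 1.03 while aroF, of aromatic synthesis, rose by 2.05 ± 0.14. Of 15 SOS genes, 11 rose and 1 fell, with recN up by 1.07 ± 0.14 and sbmC, a gyrase inhibitor gene, at -2.32 ± 0.21 on the log2 scale (camera adjusted p = 0.0272, and adjusted p = 0.515 with an estimated correlation). Of 13 heat shock genes, 9 rose and 4 did not pass, and dnaK rose by 1.6 ± 0.25 (camera adjusted p = 0.0292, and adjusted p = 0.536 with an estimated correlation). Of 10 Rcs genes outside the colanic acid operon 7 rose, with rcsA up by 1.81 ± 0.23 on the log2 scale (camera adjusted p = 0.028, and adjusted p = 0.515 with an estimated correlation). Without vector replicate 1, 4 of the Rcs genes rose.

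Among the genes that fell with wild-type pIV, treB, the trehalose transporter gene, went from 3507 ± 814 to 14.1 ± 0.07 CPM (log2 fold change -7.96 ± 1.19, adjusted p = 0.000724). Of 21 sugar uptake and glycerol genes 20 fell and 1 did not pass. They included treC (-7.51 ± 1.26), mglB (-5.88 ± 0.98) and rbsA (-4.45 ± 0.50), and the list gave camera adjusted p = 6.61e-07, and adjusted p = 0.515 with an estimated correlation. In the maltose regulon 9 of 10 genes fell and malZ rose, with malE at -6.05 ± 0.96 and its activator malT at -3.11 ± 0.30 (camera adjusted p = 0.00458, and adjusted p = 0.515 with an estimated correlation). Of 15 TCA cycle genes 14 fell, and sdhB went from 1356 ± 581 to 162 ± 15.7 CPM. All 13 NADH dehydrogenase I genes fell, with nuoA at -1.99 ± 0.35. The TCA cycle list gave camera adjusted p = 0.000288 and the NADH dehydrogenase I list 0.000681, and each gave adjusted p = 0.515 with an estimated correlation. In vector replicate 2 the TCA cycle median lay 0.72 below the vector mean, and in replicates 1 and 3 it lay 0.42 and 0.38 above it.

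Anaerobic respiration and fermentation genes fell in 21 of 32 cases with wild-type pIV, rose in 5 and did not pass in 6. The nitrate and nitrite genes narK (-7.36 ± 0.91), nirB (-4.37 ± 0.45) and nirD (-2.59 ± 0.25) and the formate dehydrogenase gene fdnG (-2.83 ± 0.10) were among those that fell (camera adjusted p = 0.000681, and adjusted p = 0.479 with an estimated correlation). Of 24 RpoS and acid resistance genes, 11 fell and 13 did not pass, among them hdeB (-2.06 ± 0.23) and gadX (-1.26 ± 0.20) (camera adjusted p = 0.00823, and adjusted p = 0.515 with an estimated correlation). Of 13 outer membrane protein genes 8 fell and 3 rose. The porin genes ompW (-3.41 ± 0.22) and ompF (-1.66 ± 0.32, chosen after its values were seen) fell, and the ferrichrome receptor gene fhuA, already counted with iron, rose (camera adjusted p = 0.0451, and adjusted p = 0.515 with an estimated correlation). Outside the lists, garP, a galactarate transporter gene (-6.54 ± 0.30), napF (-5.46 ± 0.60), yjfO (-5.85 ± 0.76) and ychH (-5.58 ± 0.83) fell, and ycfJ rose by 4.04 ± 0.15.

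The remaining lists were not called in wild-type pIV. Of 16 Cpx genes 9 rose and 2 fell (camera adjusted p = 0.101), with cpxP up by 2.71 ± 0.30 and dsbA at -0.69 ± 0.10 on the log2 scale, and without vector replicate 1, 5 Cpx genes rose. In the BaeSR list 3 rose and 1 fell, and in the sigma E list 3 rose and 6 fell. Colanic acid genes rose in 2 of 11 cases, wcaL by 0.93 ± 0.19 and wcaI by 0.81 ± 0.24, and the other 9 did not pass. The wcaI call was lost without vector replicate 1, vector replicate 3, wild-type pIV replicate 1 or wild-type pIV replicate 2 (adjusted p up to 0.0777). Among flagella and chemotaxis genes 4 rose and 7 fell, and flhC, a subunit of the master regulator, fell by 2.01 ± 0.16. Of the curli genes 3 rose and 1 fell, and of the type 1 fimbriae genes 2 rose and 1 did not pass. For protein export 11 rose and 4 fell, for phospholipid and fatty acid synthesis 5 rose and 5 fell, and for branched-chain amino acids 9 rose and 2 fell. For purine and pyrimidine synthesis 10 rose and 3 fell, for toxin-antitoxin genes 9 rose and 7 fell, and for copper and zinc 2 rose, with the zinc exporter gene zntA up by 2.29 ± 0.19. In the ATP synthase list 3 fell and in the terminal oxidase list 4 fell. In the lipid A list 4 rose and 2 fell, in the PhoPQ list 1 rose and 3 fell, and in the Kdp list 2 rose.

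Adjusted over the list alone, the wild-type pIV counts were as above except for 1 more rise in each of Cpx (10), BaeSR (4), arginine (7) and toxin-antitoxin (10), 1 rise of colanic acid genes, 1 of copper and zinc genes, 3 rises and 3 falls of flagella genes, and 10 falls of RpoS genes. With total-count scaling 931 genes were higher and 417 lower, 69.1% of calls higher against 52.5% in the main test, and the median log2 fold change of all genes moved from -0.01 to 0.29, to which the fold changes above are relative. That scaling ended the list calls of Rcs regulon without colanic acid genes, SOS response, outer membrane proteins, arginine synthesis, tryptophan and aromatic amino acid synthesis and histidine synthesis, and leaving out 1 library ended those of outer membrane proteins (without vector replicate 1, vector replicate 2 or wild-type pIV replicate 3, adjusted p = 0.0847, 0.0935 and 0.0546), heat shock chaperones and proteases (without vector replicate 2, 0.0935) and Rcs regulon without colanic acid genes (without pIV-E292K replicate 1, 0.0562).

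**Figure D2:**
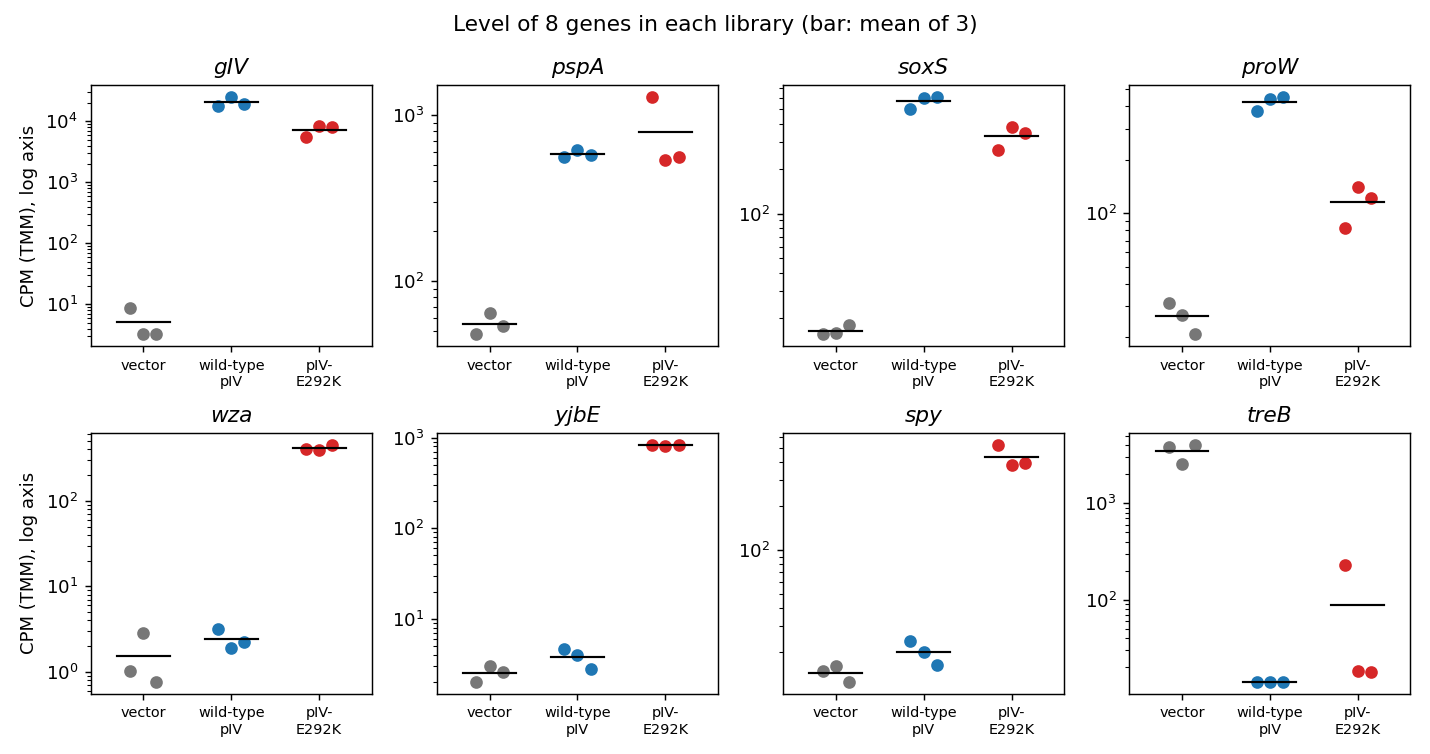
Level of 8 genes in each library, as CPM with TMM scaling on a log axis, with 3 points per group and a bar at the mean. pspA and soxS lie higher in every pIV library than in every vector library, wza, yjbE and spy lie higher in the 3 pIV-E292K libraries than in the other 6, and treB lies at 227 CPM in pIV-E292K replicate 1 against 18 and 17.6 CPM in replicates 2 and 3.

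pIV-E292K was compared with the same vector libraries to ask which host genes differ when the altered channel is made. Colanic acid capsule genes and the other genes of the Rcs envelope stress system rose most, by a median of 6.45 and 5.56 on the log2 scale. In the Cpx and BaeSR envelope responses 14 of 16 and 6 of 7 genes rose, as did 5 of 7 phage shock genes, 16 of 17 iron genes and 4 of 4 osmoprotectant genes. In anaerobic respiration 20 of 32 genes fell, in sugar uptake 14 of 21, in the TCA cycle 7 of 15 and in NADH dehydrogenase I 6 of 13. Of 4188 features, 1008 were higher and 876 lower (edgeR adjusted p under 0.05), and the groups did not overlap for 47.7% of features, where chance gives 10%. A fit of only the 6 libraries compared, without wild-type pIV, called 703 higher and 575 lower.

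All 11 measured colanic acid genes rose with pIV-E292K. wza, of the capsule export channel, went from 1.56 ± 1.15 to 419 ± 32.8 CPM (log2 fold change 8.03 ± 0.53, adjusted p = 1.83e-05). wzb rose by 7.72 ± 0.57, gmm by 7.28 ± 0.36, wzc by 6.86 ± 0.51 and wcaI by 6.68 ± 0.29 (camera adjusted p = 1.64e-10, and adjusted p = 0.275 with an estimated correlation). All 10 Rcs genes outside that operon rose. yjbE went from 2.52 ± 0.49 to 822 ± 21 CPM (8.34 ± 0.26), yjbF rose by 7.03 ± 0.30, yjbG by 6.87 ± 0.30, rcsA, a capsule gene activator, by 6.55 ± 0.28 and osmB by 5.92 ± 0.22 (camera adjusted p = 1.66e-10, and adjusted p = 0.213 with an estimated correlation). Of 16 Cpx genes 14 rose and 2 did not pass. The periplasmic chaperone gene spy went from 14.4 ± 1.85 to 436 ± 81.1 CPM (4.92 ± 0.22) and cpxP from 65.9 ± 17.7 to 1608 ± 535 CPM (4.61 ± 0.32), and yqaE rose by 2.59 ± 0.14 and yebE by 2.35 ± 0.19 (camera adjusted p = 1.19e-07, and adjusted p = 0.0998 with an estimated correlation). Of 7 BaeSR genes, a list that shares spy with Cpx, 6 rose, with the efflux pump genes mdtA up by 1.56 ± 0.14 and mdtB by 1.21 ± 0.13 (camera adjusted p = 0.000673, and adjusted p = 0.333 with an estimated correlation).

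With pIV-E292K 5 phage shock genes rose and 2 fell. pspA rose by 3.84 ± 0.36, pspB by 3.41 ± 0.19, pspC by 3.30 ± 0.18, pspD by 3.30 ± 0.21 and pspG by 3.03 ± 0.25, while pspE fell by 1.46 ± 0.27 and pspF by 0.85 ± 0.14 (camera adjusted p = 0.0167, and adjusted p = 0.582 with an estimated correlation). pspA lay at 1285 CPM in pIV-E292K replicate 1 against 534 and 559 CPM in the other 2. soxS rose by 4.35 ± 0.17, 1 of 5 oxidative genes that rose, while 7 did not pass. Of 17 iron genes 16 rose, sufA by 2.30 ± 0.22 and fhuA by 2.68 ± 0.32 (camera adjusted p = 2.53e-07, and adjusted p = 0.432 with an estimated correlation). All 4 osmoprotectant genes rose, proW by 2.14 ± 0.23 (camera adjusted p = 0.00370, and adjusted p = 0.411 with an estimated correlation). Heat shock genes rose in 10 of 13 cases, dnaK by 1.53 ± 0.25 (camera adjusted p = 0.00727, and adjusted p = 0.630 with an estimated correlation). For protein export 12 of 18 rose and 4 fell, with the lipoprotein genes lspA and lolA up by 2.0 ± 0.12 and 1.21 ± 0.10 (camera adjusted p = 0.0328, and adjusted p = 0.432 with an estimated correlation). In the sigma E list 5 rose, 1 fell and 10 did not pass.

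Ribosomal protein genes rose in 29 of 53 cases with pIV-E292K, and their median lay 0.28 above the vector mean in replicate 1 against 0.80 and 0.95 in replicates 2 and 3 (camera adjusted p = 1.56e-05, and adjusted p = 0.645 with an estimated correlation). Without vector replicate 1, 16 of them rose. Methionine genes rose in 10 of 13 cases, metF by 3.36 ± 0.34, and arginine genes in 7 of 8 (camera adjusted p = 0.00112 and 0.00370). With an estimated correlation both of these lists had adjusted p = 0.432. All 3 tested histidine genes rose, hisG by 1.8 ± 0.20 (camera adjusted p = 0.00727, and adjusted p = 0.429 with an estimated correlation). Branched-chain amino acid genes rose in 8 of 12 cases and aromatic ones in 6 of 9, with tnaB, chosen after its values were seen, at -3.50 ± 0.92 (camera adjusted p = 0.0167 and 0.0222). With an estimated correlation these lists both had adjusted p = 0.275. tnaB lay at 35.9 ± 40.6 CPM with pIV-E292K, an SD above its mean. The 3 measured genes of the argF-lac strain check rose, mhpD by 3.06 ± 0.29 (camera adjusted p = 0.0223, and adjusted p = 0.467 with an estimated correlation). Whether they lie inside the region deleted in MC4100 was not tested. mhpE rose by 0.74 ± 0.20, a call lost without vector replicate 1, vector replicate 3, pIV-E292K replicate 2 or pIV-E292K replicate 3 (adjusted p up to 0.0624).

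Of 32 anaerobic genes 20 fell, 4 rose and 8 did not pass with pIV-E292K. narK fell by 4.78 ± 0.81, narG by 4.40 ± 0.64, nirB by 4.23 ± 0.45 and fdnG by 3.06 ± 0.10 (camera adjusted p = 4.89e-05, and adjusted p = 0.122 with an estimated correlation). Of 21 sugar genes 14 fell and 3 rose; treB (-5.33 ± 1.05) and treC (-4.59 ± 1.10) fell, while galP (1.91 ± 0.16) and galT (0.96 ± 0.18) rose (camera adjusted p = 0.00575, and adjusted p = 0.645 with an estimated correlation). treB lay at 87.6 ± 121 CPM with pIV-E292K, an SD above its mean, and was highest in replicate 1. In pIV-E292K replicate 1 narK, narG and treC lay at 47.5, 90.3 and 177 CPM, against 13.2, 22 and 11.2 CPM in replicate 2 and 4.87, 16.4 and 12 CPM in replicate 3. Without replicate 1 the log2 fold change of narK, pIV-E292K against vector, was -6.03, the log2 fold change of narG, pIV-E292K against vector, -5.55, and the log2 fold change of treC, pIV-E292K against vector, -7.10. TCA cycle genes fell in 7 of 15 cases and NADH dehydrogenase I genes in 6 of 13 (camera adjusted p = 0.00101 for each, and adjusted p = 0.608 for each with an estimated correlation). Their medians lay at -0.43 and -0.20 in pIV-E292K replicate 1, against -1.97 and -1.72 in replicate 2 and -2.14 and -1.86 in replicate 3. Without pIV-E292K replicate 1, 14 TCA cycle and 13 NADH dehydrogenase I genes fell, and without vector replicate 1, 3 of the latter. Of the 10 maltose genes 4 fell, 1 rose and 5 did not pass, with malE, chosen after its values were seen, at 305 CPM in replicate 1 against 96 and 18.7 CPM in the other 2. Without replicate 1, 7 maltose and 8 outer membrane genes fell. Also lower were garD (-4.52 ± 0.31), garL (-4.51 ± 0.41), garP (-5.64 ± 0.29), napF (-4.97 ± 0.59) and napD (-4.51 ± 0.56), the porin gene ompF (-3.11 ± 0.34) and flhC (-4.02 ± 0.18).

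The other lists were not called with pIV-E292K. Among RpoS genes 5 rose and 3 fell, with osmY up by 3.14 ± 0.50 and katE by 3.47 ± 0.56 on the log2 scale. katE lay at 230 CPM in replicate 1 and at 54.9 and 58.4 CPM in the other 2, and without replicate 1, 5 RpoS genes rose and 11 fell. Of outer membrane genes 2 rose and 5 fell. In the SOS list 3 rose and 2 fell, and in the toxin-antitoxin list 5 rose and 8 fell. Adjusted over the list alone, the counts in the lists called were as above except for 15 rises in Cpx, 1 fall in heat shock, 13 rises in protein export, 9 falls in the TCA cycle, 8 falls in NADH dehydrogenase I, 34 rises in the ribosome and 7 in the aromatic list. In the other lists of these paragraphs it changed the counts of maltose (6 falls), SOS (1 fall) and toxin-antitoxin genes (10 falls).

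With total-count scaling 803 genes were higher and 205 lower in pIV-E292K against vector, 79.7% of calls higher against 53.5%, and the median of all genes moved from -0.01 to 0.40. That scaling ended the list calls of protein export and lipoprotein sorting, branched-chain amino acid synthesis and tryptophan and aromatic amino acid synthesis, and leaving out vector replicate 2 ended those of protein export and lipoprotein sorting (adjusted p = 0.0721) and tryptophan and aromatic amino acid synthesis (0.0611), as did a filter of at least 10 CPM in 3 libraries (0.0692 for each).

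**Figure D3:**
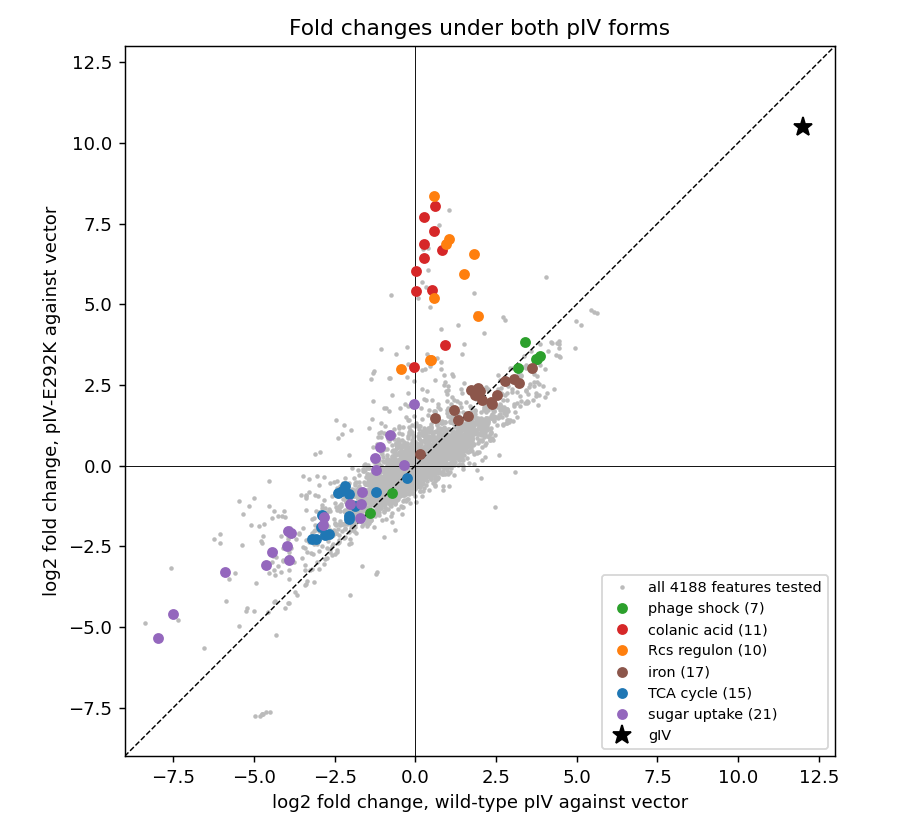
Log2 fold change against vector of each of the 4188 features tested, for wild-type pIV (horizontal axis) and pIV-E292K (vertical axis), with 6 gene lists and gIV coloured and the line of equal change dashed. Colanic acid and Rcs genes lie above the line, phage shock and iron genes near it, and the cluster at the lower left holds features with no symbol.

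The calls of the comparisons with vector overlapped. In all, 795 genes were higher and 703 lower with both pIV forms, 1498 the same way, and 48 went opposite ways. Lists drawn independently would share 312 and 245 genes. In 50 simulations of unchanged groups that shared a simulated vector group, no gene was called in both comparisons, by edgeR. With no gene changed in the simulations, hardly any call was possible. Their overlap therefore cannot show how much of the observed overlap comes from the shared controls. Log2 fold changes had a Spearman correlation of 0.817 across genes, against a mean of 0.466 in the simulations, and a covariance of 1.32 against 0.0612. Genes are not independent replicates, and since the 3 controls could not be split into parts with at least 2 libraries each, part of the excess may come from the shared controls.

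pIV-E292K was compared with wild-type pIV to ask what differs between cells that make the altered and the unaltered channel. The pIV-E292K mean of gIV was 34.7% of the wild-type mean. A fall toward the vector level therefore cannot be credited to the substitution rather than to less gIV. Colanic acid and Rcs genes were higher with pIV-E292K by a median of 6.0 and 4.51 on the log2 scale. In the Cpx list 12 of 16 genes were higher, in BaeSR 5 of 7, in maltose 6 of 10, in RpoS 11 of 24, in sigma E 5 of 16 and in sugar uptake 7 of 21. In the methionine list 10 of 13 genes were lower, in osmoprotectant uptake 4 of 4, in SOS 9 of 15 and in toxin-antitoxin 11 of 22, and no phage shock gene passed the threshold. Of 4188 features, 442 were higher and 547 lower (edgeR adjusted p under 0.05), and groups did not overlap for 56.2% of features, where chance gives 10%.

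All 11 colanic acid genes rose from wild-type pIV to pIV-E292K. wza went from 2.43 ± 0.63 to 419 ± 32.8 CPM (log2 fold change 7.42 ± 0.52, adjusted p = 4.16e-05), wzb rose by 7.45 ± 0.56, gmm by 6.71 ± 0.34 and wcaA by 6.17 ± 0.44 (camera adjusted p = 4.01e-16, and adjusted p = 0.247 with an estimated correlation). All 10 Rcs genes rose, yjbE from 3.80 ± 0.94 to 822 ± 21 CPM (7.75 ± 0.26), yjbF by 5.98 ± 0.28 and osmB by 4.42 ± 0.20 (camera adjusted p = 3.38e-15, and adjusted p = 0.141 with an estimated correlation). In the Cpx list 12 of 16 rose, spy by 4.46 ± 0.21, ycfS by 2.41 ± 0.26 and the disulfide oxidase gene dsbA by 1.68 ± 0.10 (camera adjusted p = 7.52e-08, and adjusted p = 0.0934 with an estimated correlation). BaeSR genes rose in 5 of 7 cases (camera adjusted p = 4.78e-05, and adjusted p = 0.336 with an estimated correlation). In the sigma E list 5 rose and 11 did not pass, with the chaperone gene fkpA up by 1.67 ± 0.20 and the protease gene degP by 2.14 ± 0.45 on the log2 scale (camera adjusted p = 0.00142, and adjusted p = 0.470 with an estimated correlation). The degP call was lost without wild-type pIV replicate 2 (adjusted p = 0.0547), and degP is also a member of the Cpx list. The lipoprotein genes lolA and lolB rose by 1.39 ± 0.10 and 1.14 ± 0.12.

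RpoS genes rose in 11 of 24 cases from wild-type pIV to pIV-E292K, katE by 4.06 ± 0.57, osmY by 3.36 ± 0.50 and osmC by 1.94 ± 0.22 (camera adjusted p = 0.000140, and adjusted p = 0.451 with an estimated correlation). The list median, relative to the vector mean, was 0.20 in pIV-E292K replicate 1, 0.01 and -0.28 in replicates 2 and 3, and -1.06 to -1.0 with wild-type pIV. The katE difference rests in part on pIV-E292K replicate 1, where katE lay well above its level in replicates 2 and 3, as given above. Of 10 maltose genes 6 rose (camera adjusted p = 0.000553, and adjusted p = 0.411 with an estimated correlation). Their median, relative to the vector mean, was -0.69 in pIV-E292K replicate 1, -1.32 and -1.90 in replicates 2 and 3, and -1.97 to -1.82 with wild-type pIV. malE rose by 3.92 ± 0.87, a call lost without wild-type pIV replicate 1, 2 or 3 (adjusted p up to 0.0678). Its log2 difference lay between 2.64 and 4.44 over the 9 fits that left out a library. Sugar genes rose in 7 of 21 cases, galP by 1.94 ± 0.16 and galT by 1.75 ± 0.19 (camera adjusted p = 4.71e-06, and adjusted p = 0.451 with an estimated correlation). The sugar median was -0.87 in pIV-E292K replicate 1, -1.95 and -2.66 in replicates 2 and 3, and -2.79 to -2.60 with wild-type pIV. Without pIV-E292K replicate 1, 6 maltose and 7 sugar genes rose, and the median log2 fold change of the sugar list went from 1.49 to 0.61. treB, chosen after its values were seen, had a log2 difference of 2.63 ± 0.93 (adjusted p = 0.0756). In the PhoPQ list 3 of 5 rose, with slyB up by 0.92 ± 0.16 on the log2 scale (camera adjusted p = 0.0216, and adjusted p = 0.403 with an estimated correlation). No TCA cycle or NADH dehydrogenase I gene passed, and the lists were not called (camera adjusted p = 0.0554 and 0.261). The TCA cycle list was called without vector replicate 1, pIV-E292K replicate 2 or pIV-E292K replicate 3 (adjusted p = 0.0499, 0.0271 and 0.00362) and the NADH dehydrogenase I list without pIV-E292K replicate 3 (0.0229).

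Methionine genes fell in 10 of 13 cases from wild-type pIV to pIV-E292K, metI by 1.22 ± 0.12 and metE by 0.81 ± 0.10 (camera adjusted p = 0.000205, and adjusted p = 0.403 with an estimated correlation). All 4 osmoprotectant genes fell, proW by 1.88 ± 0.22 and proV by 1.63 ± 0.24 (camera adjusted p = 0.00129, and adjusted p = 0.403 with an estimated correlation), while the proP call was lost without wild-type pIV replicate 1, 2 or 3 (adjusted p up to 0.0714). SOS genes fell in 9 of 15 cases, recN by 0.82 ± 0.14 (camera adjusted p = 0.000553, and adjusted p = 0.373 with an estimated correlation). Toxin-antitoxin genes fell in 11 of 22 cases, the antitoxin gene relB by 0.90 ± 0.11 (camera adjusted p = 0.000382, and adjusted p = 0.403 with an estimated correlation). Purine and pyrimidine genes fell in 6 of 20 cases (camera adjusted p = 0.0419, and adjusted p = 0.560 with an estimated correlation). No ribosomal protein gene passed, while the list median was -0.43 (camera adjusted p = 8.72e-05, and adjusted p = 0.736 with an estimated correlation). By fry this list was not called (fry adjusted p = 0.151). Single genes that fell included lacIq (-3.76 ± 0.39), gfcB (-2.42 ± 0.25), pgaA (-2.29 ± 0.21) and pgaB (-1.90 ± 0.37) of a surface polysaccharide operon, ymiA (-2.13 ± 0.20), yciX (-2.13 ± 0.20), yebN (-1.88 ± 0.30) and flhC (-2.0 ± 0.16). soxS fell by 0.78 ± 0.15 and ompF by 1.46 ± 0.32, and the ompF call was lost without wild-type pIV replicate 2 (adjusted p = 0.0505).

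The phage shock genes did not pass in this comparison. pspA differed by 0.44 ± 0.32 (adjusted p = 0.338), pspB by -0.45 ± 0.17, pspC by -0.44 ± 0.17, pspD by -0.47 ± 0.19, pspE by -0.07 ± 0.27, pspF by -0.12 ± 0.14 and pspG by -0.14 ± 0.23 (list camera adjusted p = 0.335). Without pIV-E292K replicate 1, pspB, pspC and pspD were called lower (pspB at -0.68, adjusted p = 0.00251) and the phage shock (psp) list was called (adjusted p = 0.0128). No iron gene passed, with a list median of -0.04, and without that library 3 rose. Of heat shock genes only htpX, also a member of the Cpx list, passed (0.80 ± 0.15). Among the lists not called were curli (3 fell), type 1 fimbriae (2 fell), copper and zinc (1 rose, 5 fell), phosphate starvation (5 fell), phospholipid synthesis (6 fell) and flagella (1 rose, 5 fell).

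Adjusted over the list alone, the counts of pIV-E292K against wild-type pIV were as above except for 6 rises in sigma E, 7 in BaeSR, 14 in RpoS, 7 in maltose and 17 in sugar genes, and falls of 11 methionine (with 1 rise), 10 SOS, 13 toxin-antitoxin, 7 purine and pyrimidine and 7 phospholipid genes (with 1 rise). Gene counts dropped to 268 higher and 300 lower without wild-type pIV replicate 1, 235 and 221 without replicate 2, and 244 and 252 without replicate 3. With total-count scaling 241 genes were higher and 28 lower, 89.6% of calls higher against 44.7% and the list calls of purine and pyrimidine synthesis and magnesium response (PhoPQ) ended. The call of purine and pyrimidine synthesis also ended without wild-type pIV replicate 1, pIV-E292K replicate 2 or pIV-E292K replicate 3 (adjusted p = 0.0608, 0.0959 and 0.0719) and with at least 10 CPM in 3 libraries (0.0726).

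**Figure D4:**
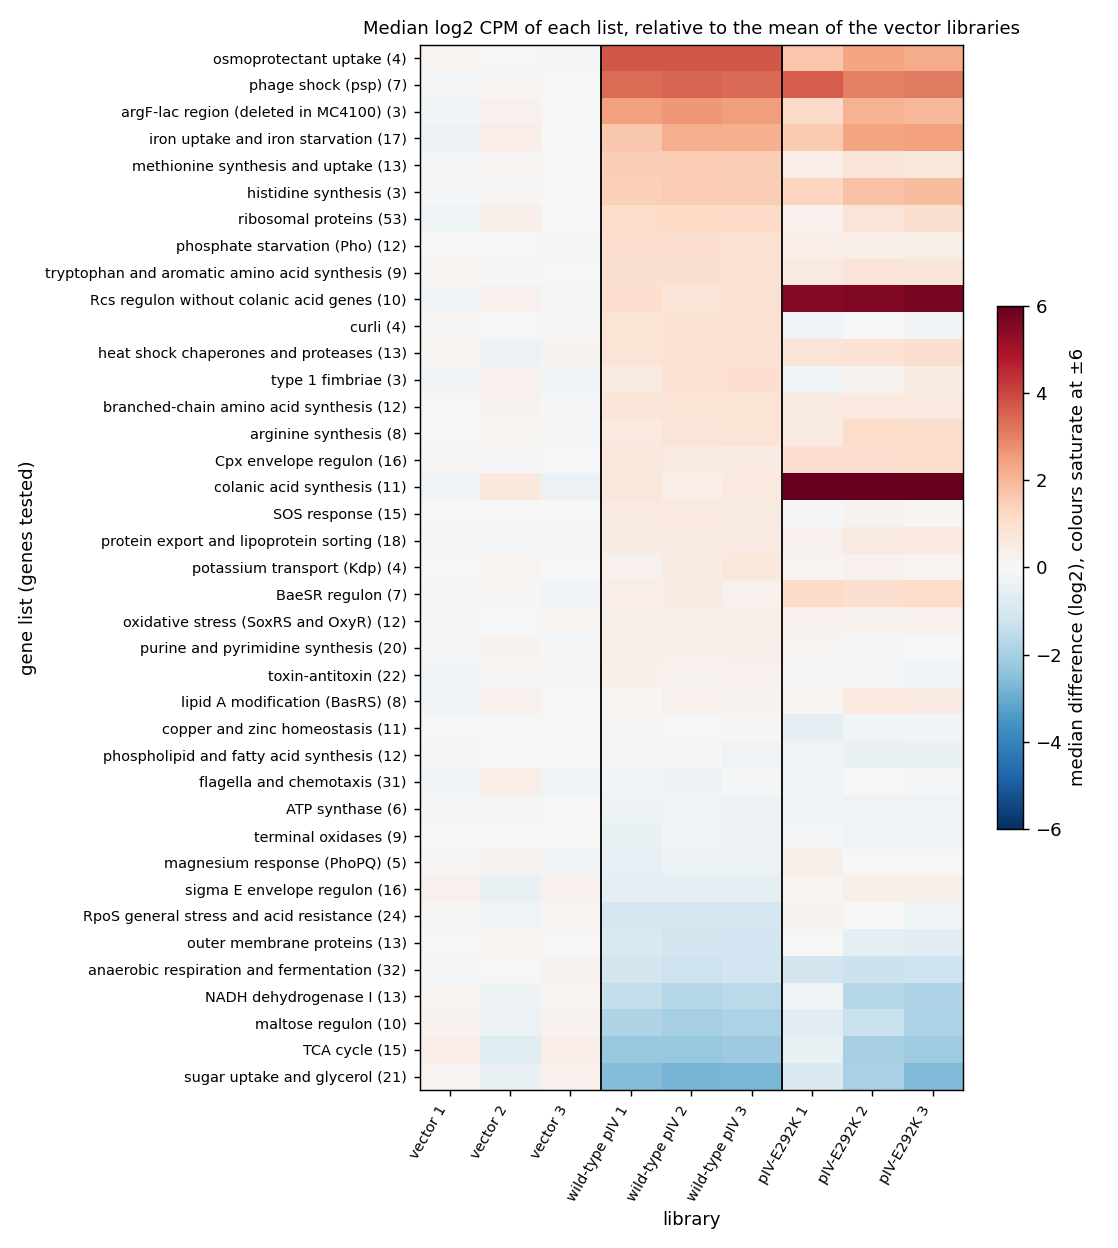
Median log2 CPM of each of the 39 gene lists in each of the 9 libraries, relative to the mean of the 3 vector libraries, with the number of genes tested in brackets and colours saturating at the ends of the scale. The colanic acid median lies between 6.09 and 6.82 in the pIV-E292K libraries and between 0.42 and 0.68 in the wild-type pIV libraries, and the phage shock median lies between 3.04 and 3.61 in all 6 pIV libraries.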

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

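The direct test between the pIV forms was planned, while the search for genes called in opposite directions, and the choice of the genes named here, came after the values were seen. Of 1546 genes called against vector in both comparisons, 48 went opposite ways with the 2 pIV forms. The direct edgeR test of pIV-E292K against wild-type pIV called all 48. That test is on the difference of the same 2 changes in the same fit, so it adds no separate support. Of these, 38 were higher with pIV-E292K and lower with wild-type pIV, 10 were the reverse, and 47 had a symbol. eco, a periplasmic protease inhibitor gene, had a log2 fold change of -0.90 with wild-type pIV and 1.77 with pIV-E292K. For ybjP the values were -1.98 and 1.12, and for yggG -0.73 and 2.18. The sugar nucleotide genes manA (-1.05 and 1.33), galU (-0.46 and 1.79) and galT (-0.79 and 0.96) were among the 38. So were rcsB (-0.87 and 0.52) and rcsD (-0.58 and 0.57) of the Rcs system and dsbA (-0.69 and 1.0) and fkpA (-0.83 and 0.84) of periplasmic folding.

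The plasmid gene lacIq was singled out by the same rule, since it differed between the pIV forms by -3.76 ± 0.39 on the log2 scale (edgeR adjusted p = 0.000364). It rose by 2.47 ± 0.37 with wild-type pIV and fell by 1.29 ± 0.35 with pIV-E292K, both against vector. The difference between the pIV forms was called in each of 9 fits that left out a library, between -4.09 and -3.46, while the fall with pIV-E292K was lost without pIV-E292K replicate 2 (adjusted p = 0.0633).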

How the results depend on the processing

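Of the alternatives here, the features left out and the pair of libraries left out were chosen after seeing the data; the others were planned. With at least 2-fold change, counts were 698 higher and 656 lower (wild-type pIV against vector), 504 and 409 (pIV-E292K against vector), 235 and 139 (pIV-E292K against wild-type pIV), and 705 the same way with both forms. With adjusted p under 0.01, 654 and 502 genes passed in pIV-E292K against vector, 227 and 204 against wild-type pIV, and 886 the same way with both. These 2 thresholds select fewer genes by construction. With total-count scaling 417 genes were lower in wild-type pIV against vector, 205 in pIV-E292K against vector, and 241 higher and 28 lower against wild-type pIV, and 759 went the same way with both. That scaling does not correct for the 7 features that took 54.3% of the counts of vector replicate 1. The TMM factor of that library was 0.455, against 1.01 to 1.18 in the others. How much of the drop this accounts for was not tested. With only the 6 libraries compared, 575 were lower in pIV-E292K against vector; the cause was not tested. Camera with an estimated correlation called 0 lists in each comparison. By fry 33 were called in wild-type pIV against vector, 25 in pIV-E292K against vector and 22 in pIV-E292K against wild-type pIV. Of the lists called in the main test, fry kept 19 of 19, 19 of 20 and 14 of 15. Sugar uptake in pIV-E292K against vector (fry adjusted p = 0.0684) and ribosomal proteins in pIV-E292K against wild-type pIV (0.151) were not kept. atpE in pIV-E292K against vector turned to 0.061 with total-count scaling (adjusted p = 0.938), a scaling that moved the median of all genes from -0.01 to 0.40.

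Leaving out each library in turn, genes higher and lower ranged from 1078 to 1375 and 902 to 1329 (wild-type pIV against vector), 776 to 1143 and 591 to 1144 (pIV-E292K against vector), and 235 to 570 and 221 to 582 (pIV-E292K against wild-type pIV). Genes the same way with both ranged from 1081 to 1920. List calls ranged from 18 to 20, 18 to 22 and 15 to 16. Of the named genes, 12, 16 and 34 in the 3 comparisons lost their call in some of these 9 fits. Over every alternative, 115 of 161, 98 of 158 and 43 of 113 called named genes stayed called in the same direction. Without the 7 abundant features, counts were 1195 and 1251, 960 and 885, and 463 and 489. Without vector replicate 1 and pIV-E292K replicate 1, they were 1276 and 1490, 1094 and 1303, and 497 and 664.

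The labels give all groups replicate numbers 1 to 3 and do not say that they pair cultures. With a replicate block, counts were 1277 and 1113, 948 and 842, and 387 and 519, with 1434 the same way with both and 17, 20 and 17 lists called. Of 9 same-number pairs, 6 had correlated deviations over 0.1 (from -0.317 to 0.448, against up to 0.499 for other pairs), and 5 of 9 libraries correlated best with their own number. In wild-type pIV against vector the phage shock (psp) list (adjusted p = 0.0557) and the outer membrane proteins list (0.0604) were not called with the block, and in pIV-E292K against wild-type pIV the type 1 fimbriae (0.0402) and TCA cycle (0.0261) lists were. A fit without rRNA and tRNA was planned but not run, because no names in the files mark such features.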

Other observations

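In this part, the tests of other splits of the libraries were planned, and the tests of the 3 patterns below were chosen after the result was seen. The genes of the next paragraph were chosen after their values were seen.

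Small RNAs outside the lists went different ways. ssrA, the transfer-messenger RNA, went from 95332 ± 8359 CPM with vector to 33966 ± 5713 with wild-type pIV and 43299 ± 9548 with pIV-E292K (edgeR log2 fold changes -1.49 ± 0.26 and -1.14 ± 0.26). rnpB, the RNA of RNase P, fell by 1.31 ± 0.21 with wild-type pIV and by 1.02 ± 0.21 with pIV-E292K. gcvB, a regulator of amino acid transport, had log2 fold changes of -2.07 ± 0.29 and -1.58 ± 0.29, and sgrS, of sugar-phosphate stress, of -2.28 ± 0.23 and -2.01 ± 0.23. csrB and csrC, which bind the regulator CsrA, had log2 fold changes of -3.12 ± 0.54 and -2.63 ± 0.19 with wild-type pIV and -1.84 ± 0.52 and -0.55 ± 0.18 with pIV-E292K, and csrC was higher with pIV-E292K than with wild-type pIV by 2.08 ± 0.19. glmY, a regulator of glucosamine-6-phosphate synthesis, rose by 1.33 ± 0.34 and 1.67 ± 0.35, and glmZ by 0.52 ± 0.17 and 1.0 ± 0.17. ssrS, the 6S RNA, had log2 fold changes of -1.18 ± 0.31 with wild-type pIV and -0.52 ± 0.30 with pIV-E292K (adjusted p = 0.0103 and 0.198), and ffs, the signal recognition particle RNA, 0.46 ± 0.35 and 0.47 ± 0.35 (adjusted p = 0.281 and 0.319). ugd, which makes UDP-glucuronate, rose by 5.53 ± 0.21 with pIV-E292K against vector and by 5.18 ± 0.21 against wild-type pIV.

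Only 10 splits of 6 libraries exist per comparison, too few for a share under 0.05. The real split called 2469 genes in wild-type pIV against vector and the highest other split 0, and 1 of 10 splits gave as many. For pIV-E292K against vector the values were 1884 and 586, the latter from vector replicates 1 and 3 with pIV-E292K replicate 1 against the rest, and 1 of 10 splits gave as many. For pIV-E292K against wild-type pIV they were 989 and 0, and 1 of 10 splits gave as many.

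The 21 colanic acid and Rcs genes were higher with pIV-E292K than with wild-type pIV by a median of 5.39 on the log2 scale. More gIV transcript is argued against, since gIV differed by -1.53 ± 0.40, a call that was lost without any 1 of the 6 libraries. Without pIV-E292K replicate 1 the median was 5.52, which argues against that library as the source. The residue may be the source, but another difference between the strains stays open, since lacIq on the plasmid differed by -3.76 ± 0.39. The plasmid feature RNAI differed by -1.84 ± 0.46 (edgeR adjusted p = 0.0230), a call lost without wild-type pIV replicate 2 or 3. The plasmid features RNAII (1.02 ± 0.34) and cat (-1.24 ± 0.43) did not pass (edgeR adjusted p = 0.0616 and 0.0689).

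pIV-E292K replicate 1 lay apart from replicates 2 and 3. RNA from a vector culture is argued against: the TCA cycle genes would need a vector share of 68.3%, and the colanic acid and Rcs genes lay 1.51 above the level that share predicts (median, log2). A different state of that culture could account for it and stays open. Its deviations had a Pearson correlation across genes of -0.65 (Spearman -0.62) with the difference between wild-type pIV and vector, and genes are not independent replicates. With vector and wild-type pIV, raw counts of replicate 1 also differed most from the other replicates. The chi-square per degree of freedom was 6911 and 6296 against 432, and 510 and 503 against 25.1. By Spearman correlation, however, vector replicates 1 and 3 were closest (0.985). Deviations of vector replicate 1 correlated with those of replicate 1 of wild-type pIV (0.404) and pIV-E292K (0.354). A batch shared by the replicate 1 libraries stays open, and the labels state none.

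The 28 TCA cycle and NADH dehydrogenase I genes had a median log2 fold change of -1.95 with wild-type pIV, where 14 and 13 were called lower, and -1.20 with pIV-E292K, where 7 and 6 were. Vector replicate 1 is argued against as the source, since the medians without it were -1.87 and -1.07. Different states of the cultures at harvest could account for it and stay open. In these genes pIV-E292K replicate 1 lay 1.56 above replicates 2 and 3, against -1.94 for the difference of those replicates from vector. An effect of pIV itself also stays open, as untested.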
